A study of Mus musculus with 38 samples.

How the data were processed

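The data were 38 bulk RNA sequencing libraries from mouse intestinal tract, deposited as 3 tables of read counts per gene. The Apc table held 18 libraries in 6 groups of 3, the AOM table held 12 libraries in 4 groups of 3, and the third table held 8 libraries in groups of 4. Group names combined an arm (black rice, control diet or WT) with the letters F or M of the titles, here called the sex code. The third set carried no sex code, and the name of its table held the letters FMT, which no label explained. The labels gave WT libraries no treatment, and the labels gave no age, collection time or feeding record for any library. Library columns of the Apc table were named Colon. The identity of every column was taken from the titles, and 0 columns were left unmapped.

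Per the labels, total RNA was extracted with Trizol, messenger RNA was captured with oligo(dT) beads, and libraries were sequenced on the DNBSEQ platform after PCR and rolling circle amplification. The authors deposited raw counts, whole numbers without normalization. Per the file headers, the AOM table and the third table came from featureCounts 2.0.1 in paired-end mode over exons grouped by gene, with the Ensembl 104 annotation of GRCm39. The Apc table had no command in its header. For all libraries the submitters named FastQC, fastp, HISAT2, SAMtools, featureCounts, Subread and GRCm39, with versions not given. The same 55416 gene identifiers stood in the same order in all 3 tables. A symbol was found for 52083 of them and 3333 had none. Genome positions are not given, since the tables held none and the annotation at hand was of another build.

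Total counts ran from 44.8 to 61.9 M reads in the Apc set, from 5.37 to 55.1 M reads in the AOM set, and from 66.6 to 91.1 M reads in the third set. Expression is given as CPM, counts scaled to library size, with the SD over libraries, and changes as log2 fold changes with their standard errors (SE). Reads made by PCR without molecular identifiers are not independent molecules, so binomial intervals cover counting error only.

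Each table was fitted separately with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by group, libraries were scaled with TMM factors, and quasi-likelihood F tests compared group means with 1 shared estimate of the spread per table. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested as the threshold. Contrasts over both sex codes are the mean of the F and M differences, and the interaction is the F difference minus the M difference. A joint fit of the black rice and control libraries of the Apc and AOM tables tested the difference of their diet effects. The number of tested genes was 21624 for Apc, 21192 for AOM, 20831 for the third set and 22699 for the joint fit. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which asks whether members move one way on balance, were run beside it. There were 39 lists of pathways and cell type markers, and a list needed 3 tested members. Counts of members are also given adjusted over the list alone.

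Groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 highest and 8 lowest fold changes past the threshold with a mean log2 CPM of at least 1 and 1 sign in F and M, leaving out predicted genes, pseudogenes and antigen receptor segments. It also took up to 4 members by smallest p of each list past the camera threshold. Where under 6 genes passed, it took the 5 smallest p in each direction, stated as not passing, and for F, M and interaction contrasts the 3 smallest p past the threshold. Cyp1a1, Ahrr, Cyp1b1, Tiparp, Lgr5, Axin2, Mki67, Apc and Ahr were named in every set. A count of libraries in a direction is the number of libraries of the first arm on that side of the mean of the other arm with the same sex code. Lists for hepatocytes, intestinal epithelial identity, distal colon Hox genes, and clock genes of the Dbp and Bmal1 phases were added after the data were seen, as were the Hox covariate and the repeat of the AOM fit without 1 library.

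Alternatives were DESeq2 1.42.0, limma-voom with quality weights, other size factors and low-count filters, a fold threshold, the compared groups alone, a block for the replicate number, a covariate for smooth muscle markers, and leaving out each library in turn. None of the 42 pairs of libraries within a group was identical. The fit was tested on simulated data with 200 genes changed at the spread and depth of each set. For a log2 change of 1 it recovered 49% of them in the Apc diet contrast, 3.06% in the AOM contrast, 11.3% in the AOM contrast without 1 library and 44.4% in the third set. For a log2 change of 2 it recovered 82.3%, 56.7%, 70.7% and 90.8% in the same order. Genes called without a simulated change numbered 4, 3, 4 and 15, and the 15 in the third set, beside 44 and 89 recovered, were a larger share of calls than the threshold allows on average. Regroupings of libraries were drawn within sex code, 60 for contrasts over both codes and 45 for the joint fit, and all 10 splits within a code and all 35 splits of the third set were used. Overlap between sets used the one-sided Fisher's exact test. Cyp1a1 was left out of the tests because its counts fell below the filter. Some single genes are not reported here.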

Results

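RNA was sequenced from the intestinal tract of mice in a series on colorectal cancer and black rice feeding. The Apc set held black rice, control diet and WT libraries, each with 3 libraries coded F and 3 coded M. The AOM set held black rice and control diet libraries, again with 3 libraries per diet and sex code. The third set held 4 black rice and 4 control libraries with no sex code. Median depth was 49.6 M reads in the Apc set (n = 18), 44.8 M reads in the AOM set (n = 12) and 77.4 M reads in the third set (n = 8).

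Transcripts of the sex chromosomes followed the sex codes in all 30 coded libraries. Xist, the RNA that coats the inactive X chromosome, lay between 333 and 2270 CPM in the 15 F libraries and between 0.019 and 0.848 CPM in the 15 M libraries. The sum of Ddx3y, Uty, Kdm5d and Eif2s3y, which are Y-linked, lay between 82.3 and 263 CPM in M libraries and at or below 0.396 CPM in F libraries. In the third set Xist reached at most 0.416 CPM and the Y-linked sum lay between 120 and 224 CPM, both within the range of the M libraries.

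Liver transcripts were abundant in a single library, black rice F replicate 3 of the AOM set. Alb, which encodes serum albumin, stood at 166000 CPM in it and at no more than 80.6 CPM in any of the other libraries. The hepatocyte list took 22.1% of its reads (95% exact binomial interval 22 to 22.1%), against a highest share of 0.0202% elsewhere. This library had 5.37 M reads, and the next lowest in the set had 37.9 M reads. Its mean over the list of intestinal epithelial identity was 4.11 log2 CPM, while the other AOM libraries lay between 8.2 and 9.94. The black rice contrast of the AOM set and its interaction with sex code are therefore given with all 12 libraries and with the 11 others, the second being a choice made after the data were seen. The splits of the AOM libraries used all 12.

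**Figure D1:**
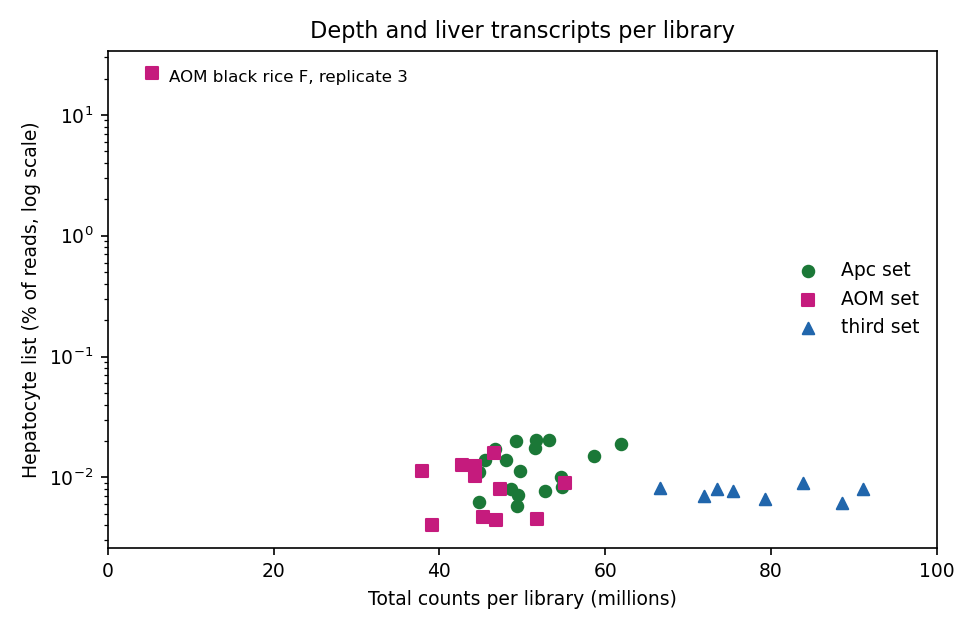
Each point is a library, with total counts in M reads on the horizontal axis and the share of reads in the hepatocyte list in percent on a logarithmic vertical axis, by set. Black rice F replicate 3 of the AOM set stands apart at 5.37 M reads and 22.1%, and all other libraries lie at or below 0.0202%.

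Black rice and control diet were first compared in the Apc set, over both sex codes. Prg2 (ENSMUSG00000027073), which encodes the major basic protein of eosinophil granules, fell by 1.74 on the log2 scale (SE 0.21, edgeR adjusted p = 0.0084). It measured 0.379 ± 0.143 CPM on black rice and 1.22 ± 0.29 CPM on control diet (SD, n = 6 each), lower in 6 of 6 black rice libraries. The immunoglobulin segment Ighv9-3 (ENSMUSG00000096459) fell by 2.88 (SE 0.42, adjusted p = 0.037), from 24.1 ± 17.5 to 3.87 ± 3.01 CPM, lower in 6 of 6. Pnliprp2 (ENSMUSG00000025091), a lipase of the pancreatic lipase family, rose by 3.71 (SE 0.48, adjusted p = 0.013), from 1.79 ± 0.691 to 74.7 ± 110 CPM, higher in 5 of 6. It was not in the exocrine pancreas list, where 4 genes were tested (mean 0.59, adjusted p = 0.095). Of these Clps differed by 1.58 (SE 0.33, adjusted p = 0.00092 over the list alone and 0.13 over all genes) and Pnliprp1 by 0.85 (SE 0.74, adjusted p = 0.53 over the list alone). Pnliprp2, Prg2 and Ighv9-3 were the 3 genes past the threshold among 21624, and Prg2 and Ighv9-3 lie outside the naming rule and were chosen after their values were seen. At an unadjusted p under 0.05 edgeR counted 2221 genes, and at the adjusted threshold limma-voom counted 17 and DESeq2 counted 193. The call of Prg2 held in 12 of 12 fits that left out a library. It was lost with the smooth muscle covariate (log2 change -1.86, adjusted p = 0.078) and with the replicate block. The call of Pnliprp2 was lost without control M replicate 1 or 3. That of Ighv9-3 was lost without any 1 of the black rice libraries or control M replicate 1 or 3. Both were also lost with that covariate, with the block and when only the compared groups were fitted. The count was 5 without control F replicate 1 or 3, 6 without control F replicate 2, 1 without control M replicate 1 or 3, and 0 with smooth muscle markers as a covariate.

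Next in rank were genes that missed the threshold. Nr1d2, a transcriptional repressor of the circadian clock, measured 148 ± 26.2 CPM on black rice and 87.3 ± 19.2 CPM on control diet (log2 difference 0.77, SE 0.14, adjusted p = 0.12), higher in 6 of 6. Npy4r, a receptor of pancreatic polypeptide, differed by 0.76 (SE 0.14, adjusted p = 0.12), higher in 6 of 6. Apoe, which encodes a lipoprotein made by macrophages among other cells, measured 269 ± 52.3 and 472 ± 66.7 CPM (log2 difference -0.81, SE 0.17, adjusted p = 0.13), lower in 6 of 6. Cyba, a subunit of the phagocyte NADPH oxidase, and Tcf7, a transcription factor of T cells and of Wnt signalling, differed by -0.78 and -0.95 with an adjusted p of 0.13 each, lower in 6 of 6.

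Markers of B and plasma cells, T and NK cells and macrophages lay lower on black rice in the Apc set. The list of B and plasma cells had a mean log2 change of -1.16 with 14 of 14 members lower, 0 past the threshold over all genes and 7 adjusted over the list alone (camera adjusted p = 3.4e-11; adjusted p = 0.56 with an estimated correlation). The constant chains Igha and Igkc measured 1170 ± 872 against 2460 ± 867 CPM and 2190 ± 1670 against 5280 ± 1880 CPM (adjusted p = 0.13 for each, log2 differences -1.46 and -1.62), lower in 6 of 6. In M libraries alone the B and plasma cell mean was -0.1 with 9 of 14 lower (adjusted p = 0.37), and the F mean was -2.21. The T and NK cell list had a mean of -0.73 with 13 of 14 members lower, 0 over all genes and 4 adjusted over the list alone (adjusted p = 1.6e-07; adjusted p = 0.64 with an estimated correlation). Among its members, Cd28 measured 2.97 ± 0.912 against 6.18 ± 2.5 CPM and Cd4 measured 9.31 ± 3.48 against 17.9 ± 7.18 CPM. Macrophage markers had a mean of -0.42 with 10 of 12 lower, 0 over all genes and 1 adjusted over the list alone (adjusted p = 0.00011; adjusted p = 0.79 with an estimated correlation), with C1qa at 45.8 ± 13.7 against 69.4 ± 16.5 CPM. Interferon response genes went the other way without passing, with a mean of 0.57 and 16 of 17 higher (adjusted p = 0.31). Smooth muscle markers stood higher in the same libraries, with a mean of 0.52 and 10 of 10 members higher, 0 over all genes and 2 adjusted over the list alone (adjusted p = 7.7e-07; adjusted p = 0.64 with an estimated correlation). Cnn1, calponin, measured 620 ± 224 against 337 ± 116 CPM and Synpo2 measured 198 ± 74.8 against 106 ± 13.4 CPM. With the smooth muscle covariate, chosen for lists after the data were seen, 4 lists passed in place of 10. Other splits of the Apc libraries gave a median of 12 lists, so the count of 10 does not set this contrast apart.

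The clock list tested higher in this contrast, with a mean of 0.75 over 8 Dbp-phase genes and -0.4 over 4 Bmal1-phase genes. Fatty acid oxidation genes lay lower over both codes but not in F libraries. The circadian clock list had a mean of 0.37, with 7 members higher and 1 lower adjusted over the list alone and 0 over all genes (adjusted p = 0.00011; adjusted p = 0.55 with an estimated correlation). Dbp and Nr1d1, whose transcripts peak together in the daily cycle, measured 21.6 ± 9.47 against 9.67 ± 3.14 CPM and 33.4 ± 16.2 against 16.1 ± 4.98 CPM, higher in 5 of 6 libraries each. The list of fatty acid oxidation had a mean of -0.57 with 15 of 15 lower, 0 over all genes and 0 adjusted over the list alone (adjusted p = 2e-04; adjusted p = 0.79 with an estimated correlation). In F libraries alone its mean was 0.33 with 10 of 15 higher (adjusted p = 0.37). Cpt1a, which carries fatty acids towards the mitochondrial matrix, measured 180 ± 51.4 against 249 ± 87.9 CPM. MHC class II (mean -0.34), tuft cell (0.33), enteric nerve and glia (0.28) and cholesterol synthesis (0.29) lists also passed, with 0 members adjusted over the list alone, at adjusted p of 0.021, 0.011, 0.034 and 0.0042 (adjusted p = 0.79 with an estimated correlation for each). Each of these calls was lost without some libraries. For MHC class II these were black rice F 3, M 1 and M 2 and control F 3, M 2 and M 3, with an adjusted p of up to 0.23. For tuft cells they were black rice F 1 and M 3 and control M 1, up to 0.33. For nerve and glia they were black rice F 1, F 3, M 1 and M 2 and control F 3 and M 1, up to 0.24. For cholesterol synthesis they were black rice M 3 and control M 3, up to 0.35.

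**Figure D2:**
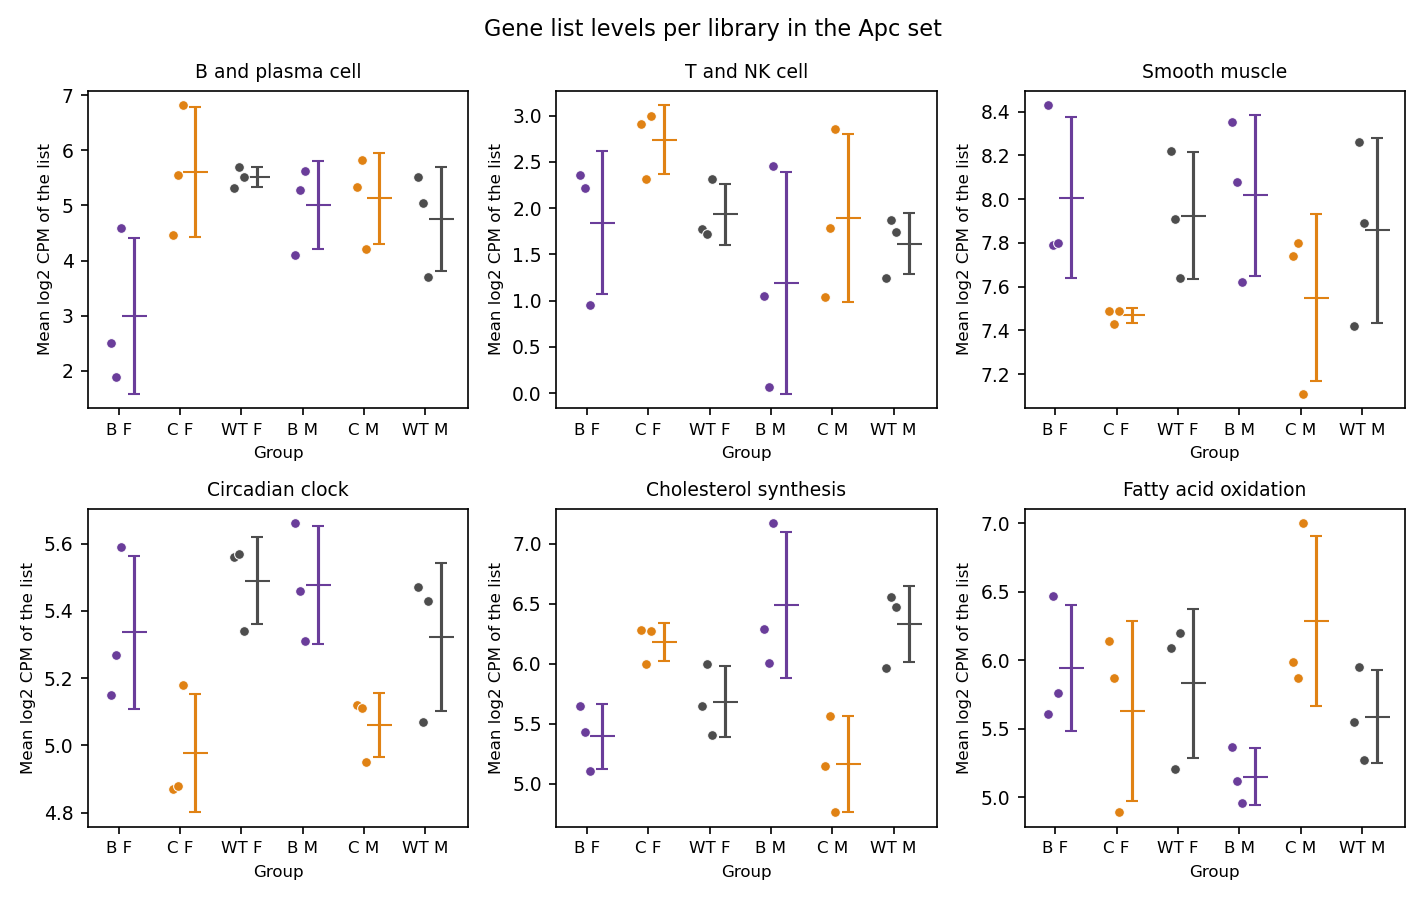
Points are libraries of the Apc set, the vertical axis is the mean log2 CPM of a gene list, and bars mark the mean and SD of each group of 3 for 6 lists. The B and plasma cell list averaged 3.0 ± 1.41 in black rice F and 5.61 ± 1.18 in control F libraries, and the cholesterol synthesis list averaged 6.49 ± 0.61 in black rice M and 5.16 ± 0.4 in control M libraries.

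Targets of the aryl hydrocarbon receptor, Wnt targets and proliferation genes showed no call as lists or over all genes in the Apc diet contrast, and Tcf7 of the Wnt list passed over the list alone (log2 difference -0.95, SE 0.2, adjusted p = 0.0042 over the list and 0.13 over all genes). Their lists had adjusted p of 0.91, 0.86 and 0.43 and mean changes of -0.23, -0.06 and -0.01, where proliferation averaged 0.44 in M and -0.45 in F, and the test of stem cell genes gave 0.99 with a mean of 0.02 and a test direction of lower. Tiparp, a repressor of the receptor, measured 31.3 ± 3.59 against 25.9 ± 4.46 CPM (adjusted p = 0.4). Ahr itself measured 22.4 ± 2.2 against 21.9 ± 2.17 CPM (adjusted p = 0.93). Ahrr and Cyp1b1 stood at 1.33 ± 0.285 against 1.52 ± 0.202 CPM and 0.28 ± 0.357 against 0.291 ± 0.184 CPM (log2 differences -0.2 and -0.35). Cyp1a1 was below the filter, with at most 2.4 CPM in an Apc library. Lgr5 differed by 0.04 (SE 0.2, adjusted p = 0.96), higher in 4 of 6 black rice libraries, and Axin2 by -0.13 (SE 0.14, adjusted p = 0.77), lower in 4 of 6. Mki67 differed by 0.22 (SE 0.27, adjusted p = 0.8), higher in 3 of 6, and Apc by 0.26 (SE 0.14, adjusted p = 0.53), higher in 5 of 6.

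Within the Apc M libraries 7 genes passed, 6 higher and 1 lower. Pnliprp2 rose by 6.19 (SE 0.75, adjusted p = 0.012), from 1.99 ± 0.996 to 146 ± 122 CPM (n = 3 each), in 3 of 3 libraries. Ciart, a clock repressor, rose by 2.11 (SE 0.33, adjusted p = 0.049) and Depp1 fell by 3.12 (SE 0.45, adjusted p = 0.041), each in 3 of 3. Lss, lanosterol synthase of the cholesterol pathway, rose from 19.2 ± 2.07 to 82.5 ± 46.3 CPM (log2 change 2.1, adjusted p = 0.049), and Fam221a, Pla2g4c and Slc29a4 rose by 1.98, 6.67 and 1.85 at the same adjusted p, all in 3 of 3. Unadjusted, edgeR counted 1846 genes, and limma-voom and DESeq2 counted 10 and 146 at the adjusted threshold. The count was 1, 2 and 1 without black rice M replicate 1, 2 and 3 and 0 without any of the control M libraries. All 7 calls were lost when only the compared groups were fitted. All but that of Pnliprp2 were lost with the replicate block and with the smooth muscle covariate. In the F libraries edgeR called 0 genes, with 2215 at an unadjusted p under 0.05, while limma-voom called 103 and DESeq2 169, and without control F replicate 1 edgeR called 4.

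Cholesterol synthesis genes lay in opposite directions by sex code. In M libraries 19 of 19 members were higher on black rice, with a mean of 1.35, 1 past the threshold over all genes and 18 adjusted over the list alone (camera adjusted p = 7.4e-26; adjusted p = 0.3 with an estimated correlation; fry adjusted p = 0.048). In F libraries 19 of 19 were lower, with a mean of -0.77, 0 over all genes and 7 adjusted over the list alone (adjusted p = 1.6e-11; adjusted p = 0.63 with an estimated correlation). The test of the difference gave a mean of -2.12 with 19 of 19 lower, 0 over all genes and 18 adjusted over the list alone (adjusted p = 8.1e-32; adjusted p = 0.16 with an estimated correlation; fry adjusted p = 0.015). Sqle, squalene epoxidase, differed by 1.67 in M (SE 0.38, adjusted p = 0.21) and by -1.11 in F (SE 0.38, adjusted p = 0.39), and was named after its values were seen. Fatty acid oxidation had a mean of -1.47 in M libraries with 15 of 15 lower and 12 adjusted over the list alone (adjusted p = 3.6e-11; adjusted p = 0.36 with an estimated correlation). Its interaction had a mean of 1.8 with 5 adjusted over the list alone (adjusted p = 7.4e-09; adjusted p = 0.37 with an estimated correlation). Proliferation genes were higher in M (mean 0.44, 25 of 25) and lower in F (mean -0.45, 23 of 25), with 0 adjusted over the list alone in either (adjusted p = 8.3e-05 and 3.9e-07; adjusted p = 0.64 and 0.72 with an estimated correlation). B and plasma cell genes had a mean of -2.21 in F with 7 of 14 adjusted over the list alone, and the interaction had a mean of -2.11 with 6 (adjusted p = 4.8e-16 and 1.1e-09; adjusted p = 0.48 and 0.34 with an estimated correlation). Gene by gene, edgeR called 0 interactions, with 1923 at an unadjusted p under 0.05, limma-voom called 19 and DESeq2 103, and edgeR called 7 without black rice F replicate 1.

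Control diet Apc libraries were compared with WT libraries, whose diet the labels did not give. Transcripts of red blood cells stood higher in the control diet libraries, with a mean of 1.92, 5 of 5 members higher, 0 over all genes and 5 adjusted over the list alone (adjusted p = 9.4e-07; adjusted p = 0.18 with an estimated correlation). Hbb-bs, a haemoglobin chain, measured 54.5 ± 36.5 against 15.3 ± 9.43 CPM. The clock list tested lower, with a mean of -0.38 (camera adjusted p = 9.4e-07, and 0.17 with an estimated correlation). Adjusted over the list alone, 6 members were lower and 2 higher, with 0 over all genes. Dbp measured 9.67 ± 3.14 against 23.3 ± 5.05 CPM and Nr1d2 87.3 ± 19.2 against 150 ± 17.3 CPM, lower in 6 of 6 libraries each. T and NK cell genes had a mean of 0.66 with 14 of 14 higher and 0 adjusted over the list alone (adjusted p = 5.8e-06; adjusted p = 0.29 with an estimated correlation). Neutrophil genes had a mean of 1.16 with 5 of 6 higher and 3 adjusted over the list alone (adjusted p = 0.0033; adjusted p = 0.18 with an estimated correlation). Smooth muscle genes had a mean of -0.4 with 10 of 10 lower and 0 adjusted over the list alone (adjusted p = 1.9e-06; adjusted p = 0.18 with an estimated correlation). Lox, which cross-links collagen, measured 5.04 ± 2.19 against 1.67 ± 0.702 CPM (log2 difference 1.56, SE 0.26, adjusted p = 0.22), higher in 6 of 6. In all 15 of 39 lists passed and none did with an estimated correlation, while edgeR called 0 genes, with 918 at an unadjusted p under 0.05, limma-voom 0 and DESeq2 23.

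Black rice against WT gave 3 genes, all with an adjusted p of 0.049. Prg2 fell by 1.37 (SE 0.21) and an immunoglobulin kappa segment (ENSMUSG00000076514) fell by 3.57 (SE 0.52), each lower in 6 of 6 black rice libraries, and Pnliprp2 rose by 3.21 (SE 0.47), higher in 5 of 6. They were named after their values were seen. All 3 calls were lost with RLE size factors, the replicate block, the smooth muscle covariate and the Hox covariate. They were also lost with limma-voom and when only the compared groups were fitted. Interferon response genes had a mean of 1.26 with 17 of 17 higher and 0 adjusted over the list alone (adjusted p = 0.00066; adjusted p = 0.86 with an estimated correlation), a call lost without black rice M 1 (0.12) or WT M 1 (0.054). B and plasma cell genes had a mean of -0.81 with 14 of 14 lower and 6 adjusted over the list alone (adjusted p = 7.6e-09; adjusted p = 0.86 with an estimated correlation). In all 5 lists passed, and 8 without black rice F 1 or WT M 2, 9 without black rice F 2, 11 without black rice M 3 and 10 without WT F 2. At an unadjusted p under 0.05 edgeR counted 1767, limma-voom called 0 and DESeq2 67. The count was 0 without black rice F 1, F 3, M 2 or M 3 or WT F 1, F 2, M 1 or M 2, and 1 without black rice F 2 or M 1 or WT M 3. Across genes, the black rice minus control and control minus WT changes from edgeR had a Pearson r of -0.47. From differences of mean log2 CPM r was -0.45, and the values that follow use that scale. Groups simulated with no change gave -0.5 because both contrasts share the control libraries. With the control libraries divided between the contrasts the mean r was -0.02, and 65 of 100 regroupings gave an r as low as the real one. Genes are not independent replicates, so no p is attached to these r.

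Black rice and control diet were compared again in the AOM set. Without black rice F replicate 3, 18 lists passed, 5 higher and 13 lower on black rice. The lists described here were among the lower ones. The MHC class II, macrophage and B and plasma cell lists lay lower on black rice. MHC class II genes had a mean of -0.75 with 7 of 7 lower and 6 adjusted over the list alone. Macrophage genes had a mean of -0.59 with 12 of 12 lower and 1 adjusted over the list alone, and B and plasma cell genes a mean of -1.41 with 14 of 14 lower and 0 adjusted over the list alone. Their camera adjusted p were 9.9e-08, 1.3e-10 and 9.9e-08, and the adjusted p with an estimated correlation were 0.45, 0.45 and 0.53. Cd74, the invariant chain of MHC class II, measured 190 ± 72.6 CPM on black rice (SD, n = 5) and 422 ± 275 CPM on control diet (n = 6). Cxcl9, a chemokine induced by interferon gamma, measured 2.01 ± 1.51 and 7.49 ± 2.9 CPM (log2 difference -1.88, SE 0.44, adjusted p = 1), lower in 5 of 5. Wnt targets had a mean of -0.99 with 18 of 21 lower and 0 adjusted over the list alone (adjusted p = 3.2e-05; adjusted p = 0.57 with an estimated correlation). Wif1 measured 38.3 ± 83.4 against 67.7 ± 56.4 CPM and Lgr5 measured 10.1 ± 12.4 against 23.4 ± 22.6 CPM. Paneth cell genes had a mean of -3.74 with 10 of 10 lower and 6 adjusted over the list alone (adjusted p = 5.8e-06; adjusted p = 0.53 with an estimated correlation), and Lyz1, the Paneth cell lysozyme, measured 52.9 ± 111 against 253 ± 221 CPM. Black rice F replicate 1 held the highest black rice value of these 3 genes, with 188 CPM of Wif1, 31.7 of Lgr5 and 252 of Lyz1, and the other 4 black rice libraries had at most 1.38, 9.53 and 5.25 CPM. Without this replicate as well, a choice made after seeing the data, the log2 differences were -6.2, -2.51 and -6.09. With 11 libraries they were -2.76, -1.25 and -3.79. Black rice F then held 1 library without both replicates, so the F part of the larger differences rests on it. Transcripts of red blood cells had a mean of -1.12 with 5 of 5 lower and 3 adjusted over the list alone (adjusted p = 4.2e-06; adjusted p = 0.45 with an estimated correlation). In the same 11 libraries, reads of identifiers without a symbol took 2.45 ± 1.59% on black rice and 4.59 ± 1.44% on control diet. Mitochondrially encoded reads took 16.3 ± 4.38% and 12.1 ± 2.42%, so both shares differed by diet alongside these lists.

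No single gene passed in the AOM set. With 12 libraries edgeR called 0 genes in the contrast over both codes, in F, in M and in the interaction, with 906, 1617, 1789 and 2627 at an unadjusted p under 0.05, limma-voom called 0 in each and DESeq2 called 22, 51, 57 and 136. Without black rice F replicate 3 edgeR called 0 in each, with 671, 716, 3019 and 3063 unadjusted. Lists past the threshold numbered 19 of 38 with 12 libraries, 5 higher and 14 lower, and 18 without that replicate. Of them 0 passed with an estimated correlation, and those described next were lower. With 12 libraries the Wnt list had a mean of -1.13 with 21 of 21 lower, and the MHC class II list a mean of -0.8 with 7 adjusted over the list alone (adjusted p = 2.4e-07 and 1.8e-08; adjusted p = 0.43 with an estimated correlation for both). The neutrophil list tested lower (adjusted p = 0.0026) although its median was 0.29 and its mean 0.01, and this call was lost without black rice F 2 (0.3) or M 1 (0.078), with an adjusted p of 0.43 with an estimated correlation. Smooth muscle genes tested lower with 12 libraries (mean -0.3, adjusted p = 0.024; adjusted p = 0.65 with an estimated correlation), a call lost without black rice F 3 (0.98) or M 1 (0.23) or control F 2 (0.063) or M 2 (0.26). Goblet cell genes (mean -0.66, adjusted p = 0.00032; adjusted p = 0.43 with an estimated correlation) passed with 12 libraries and not without that replicate (adjusted p = 0.053). The list count fell to 12 without black rice M replicate 1. Among named regulators with 11 libraries, Ahr measured 9.62 ± 3.53 against 12.4 ± 3.15 CPM, Tiparp 12.4 ± 3.8 against 15.2 ± 2.01 and Ahrr 0.326 ± 0.144 against 0.545 ± 0.147 CPM. Cyp1b1 measured 0.677 ± 0.48 against 0.364 ± 0.203, Axin2 39.8 ± 41.9 (114 in black rice F 1, at most 27.8 in the other 4) against 68.3 ± 50.5, Mki67 163 ± 83.7 against 188 ± 78.1 and Apc 80.7 ± 25.3 against 88.1 ± 45.3 CPM, and all 7 had an adjusted p of 1. Cyp1a1 reached at most 0.19 CPM.

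**Figure D3:**
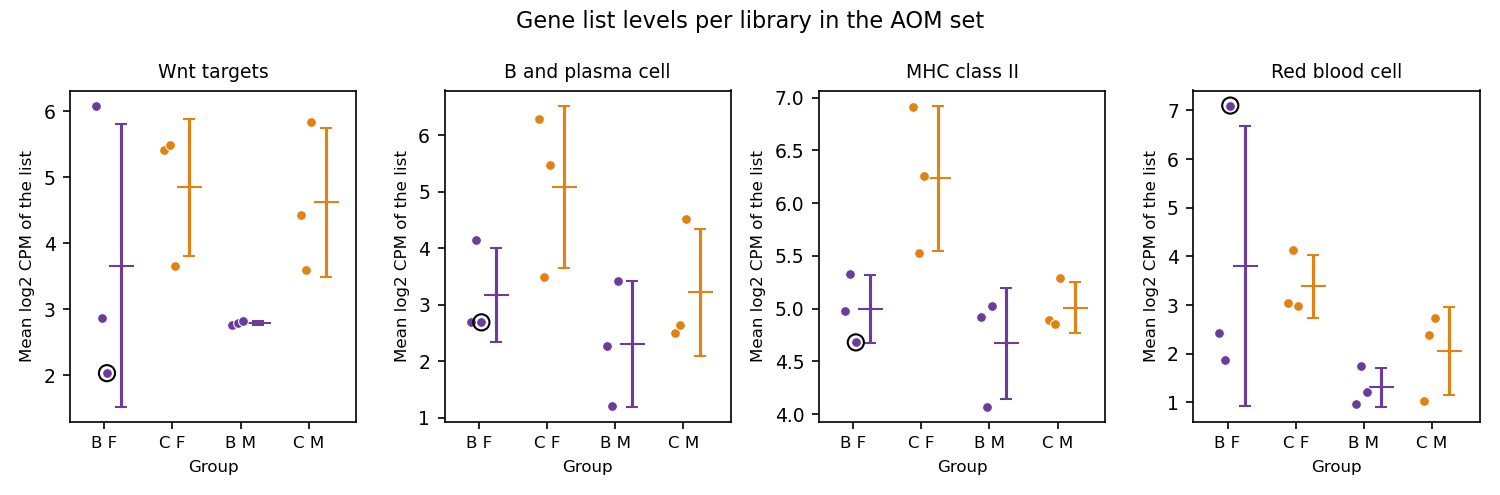
Points are libraries of the AOM set, the vertical axis is the mean log2 CPM of 4 gene lists, bars mark mean and SD of each group of 3, and a circle marks black rice F replicate 3. MHC class II averaged 5.0 ± 0.33 in black rice F and 6.23 ± 0.69 in control F libraries, and Wnt targets averaged 2.79 ± 0.03 in black rice M and 4.62 ± 1.13 in control M libraries.

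In the third set interferon response genes lay lower in black rice than in control libraries. Their list had a mean of -0.56 with 17 of 17 lower, 0 over all genes and 10 adjusted over the list alone (camera adjusted p = 1.1e-13; adjusted p = 0.49 with an estimated correlation). Control replicate 2 stood highest on this list, at a mean log2 CPM of 7.48 against 6.68 to 6.93 in the other 3 controls and 6.34 to 6.54 on black rice. Without it the mean change was -0.34, and leaving out each of the 8 libraries in turn gave an adjusted p of at most 1.6e-09. Oas2, which senses double-stranded RNA, measured 136 ± 29.4 against 254 ± 60.5 CPM (SD, n = 4 each; log2 difference -0.9, SE 0.21), lower in 4 of 4. Cxcl10, an interferon-induced chemokine, measured 5.14 ± 2.31 against 11.3 ± 1.7 CPM (log2 difference -1.14, SE 0.27), lower in 4 of 4. Adipocyte genes stood higher, with a mean of 0.96, 8 of 8 higher, 0 over all genes and 4 adjusted over the list alone (adjusted p = 0.00022; adjusted p = 0.49 with an estimated correlation), and Adipoq, adiponectin, measured 2.95 ± 1.44 against 1.15 ± 0.407 CPM. Clock genes had a mean of 0.31 with 5 higher and 2 lower adjusted over the list alone and 0 over all genes (adjusted p = 0.0098; adjusted p = 0.49 with an estimated correlation). Nr1d2 measured 117 ± 6.83 against 69.7 ± 14.3 CPM and Arntl, which encodes BMAL1, measured 27.2 ± 4.16 against 45.6 ± 16.6 CPM, in 1 direction each in 4 of 4. Immediate early genes had a mean of -0.37 with 10 of 10 lower and 0 adjusted over the list alone (adjusted p = 5.9e-05; adjusted p = 0.5 with an estimated correlation). Cholesterol synthesis had a mean of -0.21 with 16 of 19 lower and 1 adjusted over the list alone (adjusted p = 1.5e-06; adjusted p = 0.49 with an estimated correlation).

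By single genes, edgeR called 0 in the third set, with 1653 at an unadjusted p under 0.05, limma-voom called 2 and DESeq2 117, and edgeR called 1 without control replicate 2. Ifi27l2a, an interferon-induced gene, measured 22.2 ± 3.82 against 106 ± 56.9 CPM (log2 difference -2.25, SE 0.32, adjusted p = 0.34), lower in 4 of 4. Il33, an alarmin cytokine, differed by 1.12 (SE 0.18, adjusted p = 0.4) and Slfn2 by -1.55 (SE 0.3, adjusted p = 0.44), both in 4 of 4. Enteric nerve and glia genes also passed as a list, higher on black rice, where only Gfap (-0.34) and Uchl1 (-0.15) lay lower. Elavl4 (0.98) had the smallest edgeR p of this list, 0.13 adjusted over the list alone. The tuft cell and tight junction lists also passed, lower on black rice. In all 11 lists passed, where other splits of these libraries gave a median of 11.5. With an estimated correlation the smallest adjusted p of any list in this set was 0.49. Calls of the B and plasma cell list (mean 0.69, adjusted p = 0.029; adjusted p = 0.91 with an estimated correlation) were lost without black rice 1 or 2 or control 2 or 3, with an adjusted p of up to 0.66. The inflammatory cytokine list (mean -0.43, adjusted p = 0.004; adjusted p = 0.5 with an estimated correlation) was lost without control 1, at 0.076. The macrophage list (mean -0.24, adjusted p = 0.0049; adjusted p = 0.68 with an estimated correlation) was lost without black rice 3, at 0.053. Ahr differed by 0.05 (SE 0.14), Tiparp by -0.13 (SE 0.18), Ahrr by -0.12 (SE 0.39), Cyp1b1 by 0.41 (SE 0.34), Lgr5 by 0.01 (SE 0.25), Axin2 by -0.27 (SE 0.14), Mki67 by 0.23 (SE 0.21) and Apc by 0.12 (SE 0.21), with adjusted p between 0.66 and 0.99. Cyp1a1 reached at most 0.24 CPM.

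**Figure D4:**
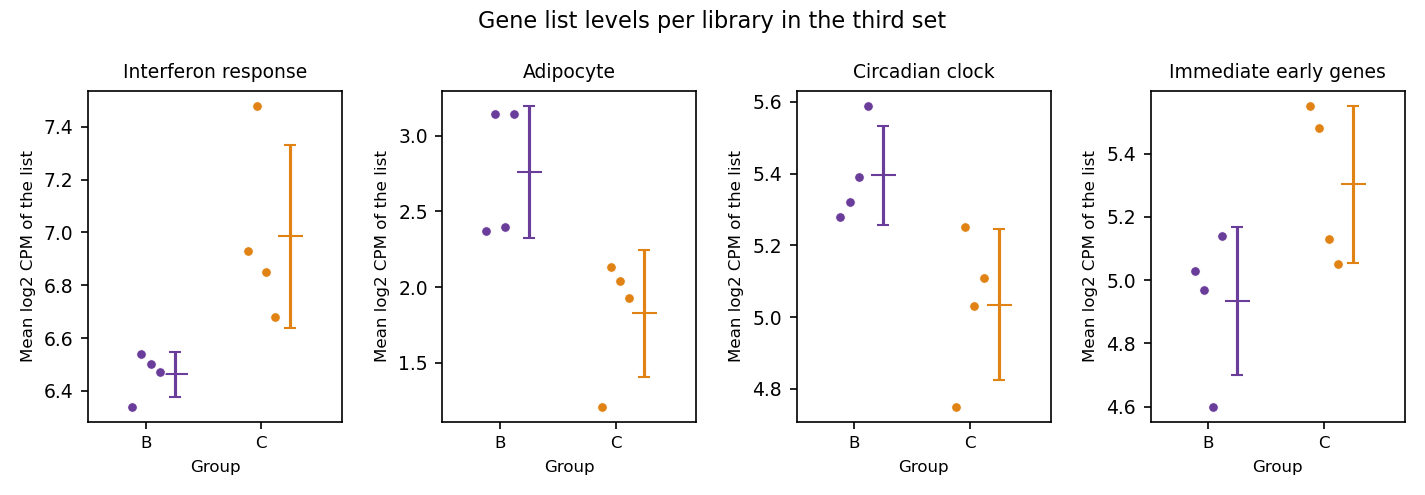
Points are libraries of the third set, the vertical axis is the mean log2 CPM of 4 gene lists, and bars mark mean and SD of each group of 4. The interferon response list averaged 6.46 ± 0.09 in black rice and 6.98 ± 0.35 in control libraries, and the clock list averaged 5.39 ± 0.14 and 5.04 ± 0.21.

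The black rice contrasts of the sets were then set side by side, and in the third set the labels name black rice and control as treatments without saying how they were given. The Apc and AOM contrasts were means over F and M libraries, while X- and Y-linked transcripts of the third set lay in the M range. The third set was not compared with the M libraries alone. The Apc minus AOM test had 0 genes by edgeR, with 1522 at an unadjusted p under 0.05, limma-voom 0 and DESeq2 8. Paneth cell genes had a mean difference of 4.95 with 10 of 10 higher and 3 adjusted over the list alone (adjusted p = 1.9e-05; adjusted p = 0.79 with an estimated correlation). Fatty acid oxidation genes had a mean of -1.75 with 15 of 15 lower and 0 adjusted over the list alone (adjusted p = 7.4e-08; adjusted p = 0.79 with an estimated correlation). Without black rice F replicate 3 of the AOM set the mean of fatty acid oxidation was -0.88 and that of Paneth cells 4.77 (adjusted p = 2.3e-05 and 8.9e-05; adjusted p = 0.9 with an estimated correlation for both). The defensins of the Paneth cell list fell below the count filter of the Apc fit. Their part of the Paneth cell means therefore rests mainly on the AOM libraries. In all 13 of 39 lists passed in this test. Without that replicate 10 passed and edgeR called 0 genes, and the stem cell (0.24), proliferation (0.15) and mitochondrially encoded (0.094) calls were lost. No gene past the threshold was shared by any pair of sets, since edgeR called 3 genes in the Apc set and 0 in the others. At an unadjusted p under 0.01, the Apc set and the third set shared 16 genes of 1 direction against 4.94 by chance and 6 of opposite direction, the Apc and AOM sets shared 5 against 1.13, and the AOM set and the third set shared 0 against 0.63. With the 11 AOM libraries these were 3 against 0.782 for Apc and AOM (one-sided Fisher's exact p = 0.03 for lower genes, and 0.00065 with 12) and 1, Cxcl9, against 0.355 for AOM and the third set. Of the 16, 15 were higher, a one-sided Fisher's exact p of 1.1e-07 that treats genes as independent, which they are not. Nr1d2, with log2 differences of 0.77 and 0.75, was the only member of the clock list among them. Others were Ncam2 (1.05 and 1.41), Unc80 (0.75 and 1.01), Rab3c (0.74 and 1.05) and Glt8d2 (0.83 and 1.05). Pla2g4c, called within the Apc M libraries, was among the 6 of opposite direction (3.58 in the Apc set and -4.02 in the third set). The 5 shared with the AOM set were immunoglobulin segments, all lower, such as Ighv1-19 at -3.06 and -2.34. From edgeR log2 fold changes over all genes, the correlation of black rice minus control was 0.08 for Apc and AOM. It was 0.05 for Apc and the third set and 0.01 for AOM and the third set. Regroupings used differences of mean log2 CPM, as do the values that follow. On that scale the correlation was 0.04, 0.08 and -0.05 in the same order, and 73, 62 and 76 of 100 regroupings gave one as large. With the 11 AOM libraries it was 0.17 for Apc and AOM (37 of 100) and 0.02 for AOM and the third set (94 of 100). By ranks, a measure added after the data were seen, it was 0.3 for Apc and the third set, where 4 of 100 regroupings gave one as large and the highest other was 0.37. It was -0.06 for Apc and AOM (66 of 100) and -0.06 for AOM and the third set (66 of 100), and 0.08 (69 of 100) and -0.01 (97 of 100) with 11 libraries.

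**Figure D5:**
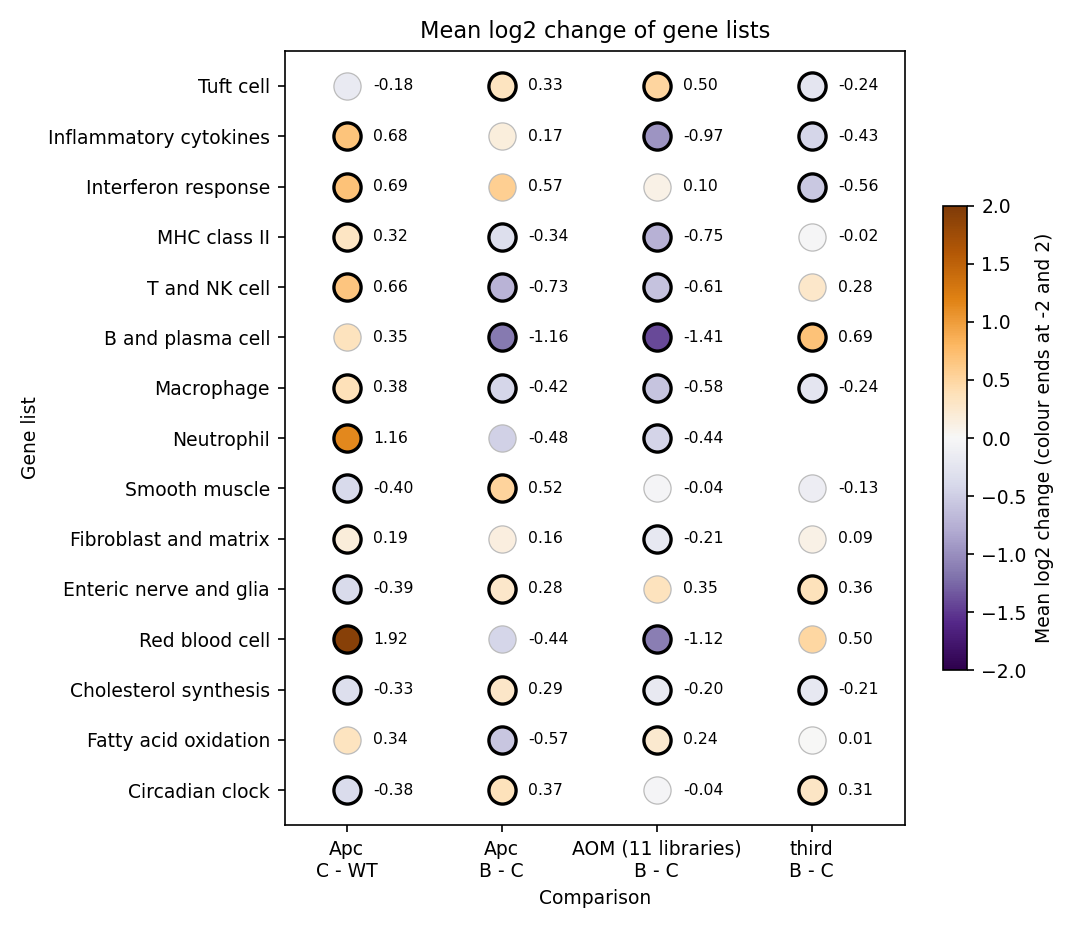
Colour gives the mean log2 change of a gene list in each of 4 comparisons for 15 lists, and a black outline marks camera adjusted p under 0.05 with the preset correlation, with the AOM column taken from 11 libraries. The clock list was outlined at 0.37 in the Apc diet comparison and at 0.31 in the third set. The macrophage and the enteric nerve and glia lists were also outlined in both with the same sign. The B and plasma cell, cholesterol synthesis and tuft cell lists were outlined in both with opposite signs.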

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

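The tests of list differences between sex codes and between sets were planned, and the choice of which lists to describe here was made after the results were seen.

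In the third set, Dixon's test was run on named genes, lists past the threshold and total counts, within the 4 black rice and the 4 control libraries. In 4 of these 60 tests a library lay far from the others, where chance gives about 1 in 20, or 3. The tests share the same libraries and many items were chosen from these data, so they are not independent. Mki67, a marker of dividing cells, stood at 7.15 in black rice 4 and between 7.67 and 7.74 in the others. Ifi27l2a stood at 7.58 in control 2 against 6.15 to 6.35, and the list of inflammatory cytokines at 0.76 in control 1 against 0.01 to 0.12.

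The diet effect in the Apc set differed between F and M libraries for 15 lists by the interaction test, with 0 lists past the threshold with an estimated correlation. The adjusted p values were 8.1e-32 for cholesterol synthesis, 3.5e-11 for proliferation, 1.1e-09 for B and plasma cells, 7.4e-09 for fatty acid oxidation, 1.5e-05 for tuft cells, 3.1e-05 for the unfolded protein and integrated stress response, 9.9e-05 for goblet cells and 0.0027 for red blood cells. They were 0.012 for small intestinal enterocytes, Paneth cells, endothelium, xenobiotic metabolism and tight junctions, 0.015 for adipocytes and 0.033 for MHC class II. Goblet cell genes had a mean interaction of -1.46 and tuft cell genes one of -1.06, both from higher levels on black rice in M libraries (means 1.34 and 0.86). With an estimated correlation the smallest adjusted p was 0.16, for cholesterol synthesis. Calls were lost without 1 library for 6 lists. These were enterocytes (control F 3 or M 3, up to 0.07), endothelium (black rice F 2 or M 1, up to 0.19), tight junctions (black rice M 2 or control F 2, up to 0.071) and xenobiotic metabolism (black rice F 2 or control F 3 or M 3, up to 0.17). The others were adipocytes (black rice F 2 or M 1 or control F 3 or M 2, up to 0.25) and MHC class II (black rice F 1, F 3 or M 3 or control F 1, F 3, M 1 or M 3, up to 0.62).

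In the AOM set the interaction test passed for 6 lists, with an adjusted p of 5.6e-06 for mitochondrially encoded genes, 0.0018 for enteroendocrine cells, 0.0028 for proliferation, 0.0082 for goblet cells, 0.018 for MHC class II and 0.025 for inflammatory cytokines. The proliferation call was lost without black rice F 1, at 0.74, and the goblet cell call without control M 2, at 0.058. MHC class II was lost without black rice F 1 or M 3 or control F 1 or M 2, at up to 0.12. Inflammatory cytokines were lost without black rice F 1, F 3, M 1 or M 2 or control F 3 or M 3, at up to 0.47. The count was 3 without black rice F 1, 15 without black rice F 2 and 10 without control F 2. Without black rice F 3, the library with liver transcripts, 7 lists passed. They were proliferation (1.7e-06), mitochondrially encoded genes (6.3e-05), enteroendocrine cells (0.013), Wnt targets (0.031), goblet cells (0.034), fatty acid oxidation (0.048) and MHC class II (0.048), and inflammatory cytokines stood at 0.057. With an estimated correlation the smallest adjusted p was 0.98, and 0.97 without that library.

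Between the Apc and AOM sets the diet effect differed for 13 lists. The adjusted p was 7.4e-08 for fatty acid oxidation, 1.9e-05 for Paneth cells, 0.00025 for goblet cells, 0.00066 for Wnt targets, 0.00073 for smooth muscle, 0.0019 for fibroblasts and matrix, 0.0027 for cholesterol synthesis and 0.0038 for xenobiotic metabolism. It was 0.0046 for the circadian clock and for mitochondrially encoded genes, 0.016 for proliferation, 0.031 for inflammatory cytokines and 0.045 for stem cells. With an estimated correlation the adjusted p values lay between 0.79 and 0.92. Without black rice F 2 of the AOM set the Wnt (0.12) and xenobiotic (0.093) calls were lost, and without black rice F 1 of that set the clock call was (0.14). Cholesterol synthesis was lost without black rice F 2 of the AOM set or M 3 of the Apc set, at up to 0.12. Mitochondrially encoded genes were lost without black rice F 3 or M 2 or control F 1 of the AOM set or black rice M 3 of the Apc set, at up to 0.094. Proliferation was lost in 8 of 24 fits that left out a library (up to 0.43), namely without black rice F 1, M 1 or M 3 or control M 1 of the Apc set, or black rice F 2, F 3 or M 2 or control F 1 of the AOM set. Inflammatory cytokines were lost in 13 of 24 (up to 0.63). They held without black rice F 3, M 1 or M 2 or control F 1 or M 1 of the Apc set, and without black rice F 1, F 3 or M 3 or control F 3, M 1 or M 2 of the AOM set. Stem cells were lost in 21 of 24 (up to 0.35), all but black rice F 1 and control F 3 and M 2 of the AOM set. Fatty acid oxidation had a mean of -1.75, and of -0.88 without black rice F 3 of the AOM set.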

How the results depend on the processing

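Counts of genes past the threshold moved with the tool and the filter, and the cause was not tested. DESeq2 gave 193 in the Apc diet contrast, 169 in F, 146 in M, 103 in the interaction, 23 for control minus WT and 67 for black rice minus WT. It gave 22 in the AOM contrast, 51 in its F, 57 in its M, 136 in its interaction, 117 in the third set and 8 for Apc minus AOM. Limma-voom gave 17 in the Apc diet contrast, 103 in F, 19 in the interaction, 0 for black rice minus WT and 2 in the third set. The CPM filter gave 3 in Apc F. Without a filter there were 23 in the Apc diet contrast, 15 in F, 16 in M, 6 in the interaction and 6 for black rice minus WT. The Hox covariate, chosen after the data were seen, gave 8 in the Apc diet contrast, 5 in F, 16 in M, 2 in the interaction and 0 for black rice minus WT. Fits of the compared groups alone gave 1 in the Apc diet contrast, 0 in M and 0 for black rice minus WT. The replicate block gave 1, 2 and 0 in the same order, and the 1 was none of Prg2 (adjusted p = 0.074), Pnliprp2 (0.074) and Ighv9-3 (0.11), which all lost their calls. The smooth muscle covariate gave 0, 1 and 0, and RLE size factors gave 0 for black rice minus WT.

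Leaving out a library in turn gave 1 to 6 genes in the Apc diet contrast, 0 to 4 in F, 0 to 2 in M, 0 to 7 in the interaction, 0 to 2 for black rice minus WT, 0 to 1 in the third set and 0 in all others. Lists ranged from 8 to 13 in the Apc diet contrast, 12 to 13 in F, 14 to 19 in M, 13 to 19 in the interaction, 11 to 20 for control minus WT and 4 to 11 for black rice minus WT. They ranged from 12 to 20 in the AOM contrast, 8 to 16 in its F, 7 to 14 in its M, 3 to 15 in its interaction, 8 to 14 in the third set and 9 to 16 for Apc minus AOM. The estimated correlation gave 0 lists in every contrast, and fry gave 0 in all but Apc M and the Apc interaction, with 1 each. The smooth muscle covariate left 4 lists in the Apc diet contrast and 7 in F. The Hox covariate gave 18 lists in AOM M and 11 in the AOM interaction, and the replicate block gave 10 in the AOM interaction. At an unadjusted p the sets shared 5 genes for Apc and AOM and 16 for Apc and the third set. With the control libraries divided the reversal r was -0.02, and a reversal over called genes alone had no genes and so no value.

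Some list directions turned. The exocrine pancreas list in Apc M turned without control M 3 (p 0.7), and leaving out a library gave 0.027 to 0.76. With the Hox covariate, goblet cells (0.48) and smooth muscle (0.24) turned in the AOM contrast and fatty acid oxidation (0.64) in AOM M. Without black rice F 3, smooth muscle (0.39) and fatty acid oxidation (0.72) turned in AOM F, where leaving out a library gave 0.0029 to 0.39 and 2.3e-07 to 0.72, all as adjusted p. Counts stayed within 1.5 times in 333 alternatives and moved in 106, and of single list and gene values 7671 stayed, 687 were weaker and 59 stronger. A count of 0 that stayed 0 was scored as staying, and edgeR called 0 genes in most contrasts. The 333 therefore includes such cases and is no measure of how stable the calls were. Most named genes had no call to lose. Where calls existed, 59 of 112 values in Apc M, 50 of 241 for black rice minus WT and 18 of 1275 in the Apc diet contrast were weaker, and 81 of 6181 values of named genes changed sign. No label links libraries by replicate number, and not every same-numbered pair deviated together, so the block was used only as an alternative. The correlation of deviations from the group mean averaged 0.03 over same-numbered pairs in the Apc set (6 of 18 over 0.1), 0.11 in the AOM set and -0.21 in the third set. Control M and WT M libraries of the same number had 0.38, 0.38 and 0.42 and correlated best with their own number, while control F and WT F had 0.14, 0.03 and -0.33. For the Apc diet contrast, black rice F and control F had 0.39, -0.01 and 0.43. Black rice M and control M had -0.09, -0.18 and -0.02.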

Other observations

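All 3 tests of the liver transcripts, the clock phase test, and the 1-library and feeding state tests of cholesterol synthesis were chosen after the results were seen, and the Hox covariate and the 5 added lists were too. The splits were planned, and the smooth muscle covariate was planned for genes and extended to lists after the data were seen.

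Reads of identifiers for which the annotation at hand held no symbol were more common in the AOM set. Their share was 4.81 ± 1.69% in control F, 4.37 ± 1.48% in control M, 3.27 ± 1.64% in black rice F and 1.47 ± 0.217% in black rice M libraries (SD, n = 3 each). A single such identifier, ENSMUSG00000119584, made up most of it, with 4.73 ± 1.68%, 4.29 ± 1.5%, 3.2 ± 1.63% and 1.4 ± 0.212% in the same order. What it encodes was not determined, since that annotation was of another build. Transcripts encoded by the mitochondrial genome took 11 ± 2.21%, 13.2 ± 2.48%, 17.1 ± 3.44% and 15 ± 4.96%, also in that order.

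Liver transcripts in black rice F replicate 3 of the AOM set were weighed first. Low depth was excluded, since the 95% exact interval of the hepatocyte share starts at 22% and the highest share elsewhere was 0.0202%. All 12 of 12 list members, among them Alb (166000 CPM), Ahsg (14200), Hpx (9910) and Fgb (8780), lay above every other AOM library, as liver RNA in this library needs. Of these 12, 5 passed 10 CPM, counted as expressed, in another AOM library and 1 is held by another list. Dilution of gut RNA by that share would lower epithelial genes by 0.36, and they fell by 5.45 (SE 0.25), so a small admixture is excluded and a largely hepatic sample may be the source, whether by dissection or by label.

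Clock genes in the Apc set were weighed second. Genes of the Dbp phase had a mean change of 0.75 (SE 0.1) with black rice, 0.8 with the smooth muscle covariate and 0.72 with the Hox covariate, which argues against muscle content or colon position as the whole cause. Genes of the Bmal1 phase had a mean of -0.4 (SE 0.22), so a different clock phase at collection could not be told apart from diet, because the labels give no time of collection. The Dbp-phase mean was -0.8 (SE 0.14) for control minus WT, -0.05 (SE 0.05) for black rice minus WT, 0.71 (SE 0.09) in the third set and -0.04 (SE 0.11) in the AOM set with 11 libraries. An effect of the diet on the clock may also contribute and was not tested apart from phase.

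Cholesterol synthesis by sex code in the Apc set was weighed last. The mean interaction was -2.12 (SE 0.2 over members, which are not independent replicates). Without black rice M 3 it came nearest to 0, at -1.69 (SE 0.17), so 1 library is excluded as the whole cause. With the Hox covariate it was -2.11. That value argues against colon position as the whole cause but cannot exclude it, since expression markers may follow position only in part. Fatty acid oxidation had a mean interaction of 1.8 (SE 0.52), in the opposite direction, and a difference in feeding state at collection may explain both, which the labels do not record. A response to diet that depends on the sex of the animals stays open and untested.

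Other splits of the libraries within sex code were fitted in the same way. For the genes of the Apc diet contrast, 1 of 60 splits, the real one, gave 3 and the highest other gave 1. For black rice minus WT 1 of 60 gave 3 and the highest other 2, and 5 of 60 gave any call. Only 60 of 200 possible splits were fitted, and many contrasts were examined this way without correction. Chance is therefore less likely for the first count but was not excluded for either. It was not excluded for their lists, with 45 of 60 splits giving 10 or more (highest other 19) and 57 of 60 giving 5 or more (highest other 18). Nor was it for the lists of the Apc interaction, with 13 of 60 giving 15 or more (highest other 20), of control minus WT, with 4 of 60 giving 15 or more (highest other 17), or of the AOM contrast, with 8 of 60 giving 19 or more (highest other 24). It was not excluded for the lists of the AOM interaction (56 of 60 for 6, highest other 27), the third set (20 of 35 for 11, highest other 20) or Apc minus AOM (19 of 45 for 13, highest other 20). Other splits had a median of 12 lists for the Apc diet contrast and 10 for black rice minus WT, above the real counts. The medians were also above the real counts for the AOM interaction (12) and the third set (11.5). They lay under the real counts for the Apc interaction (11), control minus WT (10), the AOM contrast (14) and Apc minus AOM (12). Where edgeR called 0 genes, every split gives as many by construction, so 60 of 60 for the Apc interaction, control minus WT, the AOM contrast and its interaction, 35 of 35 for the third set and 45 of 45 for Apc minus AOM say nothing about chance. The highest other gene counts there were 2, 0, 0, 0, 22 and 7. Any call at all came in 1 of 35 splits of the third set and in 2 of 45 of the joint fit, which holds black rice F replicate 3 of the AOM set, and what these few splits share was not tested.

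Within a sex code 10 splits are too few for a share under 0.05. The real and highest other counts were 7 and 0 genes and 17 and 18 lists in Apc M (1 and 2 of 10 splits as large), and 0 and 0 genes and 11 and 15 lists in Apc F (10 and 10 of 10). They were 0 and 0 genes and 10 and 22 lists in AOM F (10 and 10 of 10) and 0 and 0 genes and 11 and 16 lists in AOM M (10 and 4 of 10). The median of the other splits was 14 lists in Apc M, 13 in Apc F, 17 in AOM F and 9 in AOM M.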
